A study of Homo sapiens with 2 samples.

How the data were processed

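RNA bound by the RNA-binding protein RBM42 was sequenced from the cytoplasmic fraction of PANC-1 cells, a human cell line established from a pancreatic ductal adenocarcinoma (PDAC). Per the labels' protocols, cells were irradiated with UV light of 254 nm at 400 mJ per square centimetre, which links proteins covalently to RNA they touch, and were then separated into cytoplasm and nucleus. The cytoplasmic lysate was treated with RNase I for 5 min at 37 °C, and endogenous RBM42 was precipitated with an antibody for 4.5 h. Per the same protocols, the RNA was dephosphorylated and poly(A)-tailed on the beads, the protein-RNA complexes were resolved on a gel and excised from a membrane, and libraries were made with a SMARTer small RNA kit and an oligo(dT) primer that carried a unique molecular identifier (UMI). The 2 samples are labelled biological replicates of 1 group. No input, nuclear or control immunoprecipitation library was analysed here, so no value below is set against a background library.

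The file analysed here is a table of deletion sites from both replicates together. The submitters' processing notes name cutadapt, BWA, bedtools and the genome build hg38, without versions. The file's name says that tags were pooled, made unique and searched for deletions by CIMS (crosslink-induced mutation site) analysis, a method that looks for positions at which reads carry more deletions than random placement would give, since reverse transcriptase can skip a nucleotide that still holds a crosslinked peptide. Per the file headers, each row gives 1 position and strand, the count of unique tags overlapping it (k), the count of those tags with a deletion there (m), a false discovery rate and the count of sites with that k and at least that m. The authors deposited the false discovery rate (FDR) on the scale of a p-value, and in the table each pair of k and m has 1 FDR. How tags were collapsed, and whether the UMI was used for it, is not given in the sources used here. Because the replicates were pooled by the authors, no spread between replicates can be given, no replicate could be left out, and every interval and test below measures counting error or differences between sites or genes of 1 pooled table. Tags that are copies of 1 molecule would not be independent, and intervals and tests take no account of that.

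The depth of each library is not known from this table, which lists only positions with at least 1 deletion. Precision is therefore given per site, by k. Shares of tags carry 95% Wilson intervals, which cover counting error only.

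Sites were called passing at the authors' FDR of 0.05 or less. Positions are 1-based on hg38. Genes were named from a table of RefSeq genes of the same assembly (GRCh38.p14) that gives the start, end and biotype of each gene, but no exons, coding regions, strands or sequence. A site inside a noncoding RNA gene of at most 500 nt was given to that gene (the shortest, if several), then to an rRNA gene, then to the only gene at the position or the only protein-coding gene among several. A site in more than 1 protein-coding gene stayed unassigned and formed a class of its own. Strand was not used for naming, so a site within overlapping or antisense genes may belong to the other gene. Exon, intron and untranslated region could not be told apart. 4 results planned before the data were examined were not run for lack of a genome sequence and exon annotation: the split by 5' UTR, coding sequence and 3' UTR, the position within spliced mRNAs, the deleted base, and the 5-mers around sites. In place of the first, passing was compared between gene classes with the test planned for it. In place of the second, passing sites were counted in the first and last 200 nt of protein-coding genes. This second comparison used 7859 genes of at least 2000 nt, oriented by the strand that held at least 80.0% of at least 3 deletion sites away from both ends. The sign of each gene's difference was flipped at random in 100000 resamples (permutation test, two-sided).

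Passing and non-passing sites were compared by the Cochran-Mantel-Haenszel test within 6 bins of k (1 to 4, 5 to 9, 10 to 19, 20 to 49, 50 to 99, and 100 or more tags), with Benjamini-Hochberg adjustment over the 8 classes. Sites of 1 gene are not independent, so 95% intervals of the odds ratios were also taken from 1000 bootstrap resamples of genes (of windows of 10000 nt outside genes). Direction is stated only where that interval excludes 1. For 14 gene lists fixed before the data were examined, the share of genes with at least 1 passing site was compared with that of all other genes with a site, within quintiles of the gene's highest k (like coverage below, although the highest quintile is open and wide), with adjustment over the 14 lists. Since few genes of some lists lacked a passing site, the exact conditional form of this test was added after the data were seen (two-sided, hypergeometric within quintiles). 504 of the 505 list entries matched the gene table. The genes named below follow a rule fixed at the same time: the 10 genes with the most passing sites, the 10 genes whose best site had the most deletions, the 5 genes with the highest m/k at 20 or more tags, up to 4 members per list with the most passing sites, and RBM42. Its part for the 3 strongest sites per mRNA feature could not be applied. The part for the highest m/k was not informative, since 5537 genes tied at 100%. It named A1BG, AAK1, AAMDC, AAR2 and AATF by alphabet alone. 1 gene that the rule takes is not reported here. MYC and the chromosome 19 region were added after their values were seen.

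The stratified test was tested on simulated data. With 210997 sites and a true odds ratio of 2, the median estimate was 2.00. With no difference, 2.5% of simulations had a p under 0.05 for site classes and 5.0% for gene lists. For lists of genes with a true odds ratio of 4, among 12000 simulated genes, 77.0% of simulations reached that level before adjustment. The simulated genes passed less often than the real ones, of which 91.1% had a passing site at FDR 0.05. The 77.0% therefore does not hold for the real lists at that threshold. Simulated sites were independent of each other, so the 2.5% does not cover sites of 1 gene that pass together. Computations used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. The alternatives were other FDR thresholds, a minimum of 10 tags, leaving out sites with m/k of 0.5 or more, leaving out the mitochondrial chromosome, no stratification, 1 site per gene and another measure of coverage. Further alternatives chosen after the data were seen were 1 position per run of adjacent sites, leaving out positions in several genes, a minimum of 3 tags, finer bins of k, 20 strata of the highest k, other end windows, the strictest FDR together with the other measure of coverage, and the exact test with these choices.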

Results

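The series asked which transcripts RBM42, a protein with an RNA recognition motif, binds in the cytoplasm of PDAC cells. The pooled table of the 2 immunoprecipitations listed 210997 positions at which at least 1 tag carried a deletion, 109507 on the plus and 101490 on the minus strand. Of these, 134667 (63.8%) passed an FDR of 0.05. Passing sites lay in 12095 genes, among them 10297 protein-coding and 740 lncRNA genes, and a gene with any passing site had a median of 5. The median site was covered by 26 tags (quartiles 10 and 71) and had 9 tags with the deletion (quartiles 3 and 18). Coverage ranged from 1 to 681423 tags per site.

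At passing sites the deletion was mostly in a large share of the tags. Passing sites had medians of 21 tags and 13 tags with the deletion, and the median share of tags with the deletion was 100%, against 5.19% at sites that did not pass. In 71103 passing sites (52.8%) every tag carried the deletion, and 93254 (69.2%) had it in at least 50% of tags, a level 0.5 on the m/k scale. The share of sites with the deletion in every tag fell from 91.5% at 1 to 4 tags to 32.1% at 20 to 49 tags, 3.80% at 50 to 99 tags and 0.0120% at 100 or more tags. The share that passed was 36.0% at 1 to 4 tags, where fewer than 3 deletions never passed, 89.8% at 5 to 9 tags and 23.7% at 100 or more. Passing positions often adjoined other deletion sites: 67.2% lay next to another on the same strand, and the passing sites formed 85786 groups of linked positions, of which 46845 held 1 passing position, 31545 held 2 and 7396 held 3 or more.

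**Figure D1:**
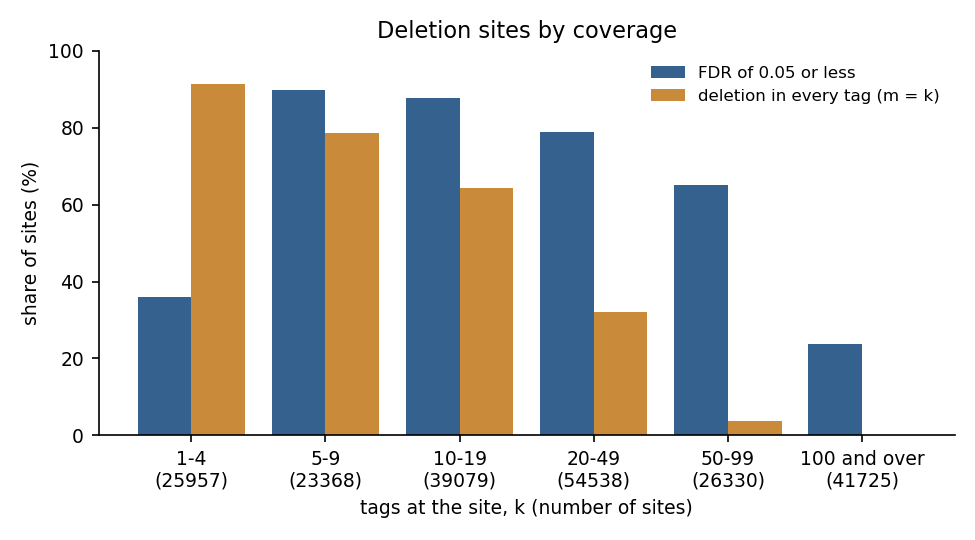
Share of deletion sites (%) that passed an FDR of 0.05 and share with the deletion in every tag, by the number of tags at the site, with the number of sites in each bin in parentheses. Sites with the deletion in every tag made up 91.5% of sites with 1 to 4 tags and 0.0120% of sites with 100 or more.

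Among sites in named genes, those with the most deletions lay in mitochondrial rRNA and in small noncoding RNAs. The highest of all sites was in RNR2, the large-subunit mitochondrial rRNA (mitochondrial chromosome, 1671 to 3229), where 182604 of 238801 tags carried a deletion at position 3180 (76.5%, 95% Wilson interval 76.3 to 76.6%). RNR2 had 545 passing sites and RNR1, the small-subunit mitochondrial rRNA, had 412, the highest numbers of all genes. Counted as groups of linked positions, they had 123 and 84, fewer than SMAD3 with 194 and NEAT1 and AKT2 with 192 each. Outside RNR2, the site with the most deletions lay in no gene named here, on the scaffold KI270733v1 at position 135091, with 65545 of 487377 tags (13.4%, interval 13.4 to 13.5%). RMRP, the RNA of the RNase MRP particle (chromosome 9, 35657750 to 35658019), had deletions in 22108 of 49668 tags at position 35657819 (44.5%, interval 44.1 to 44.9%). RNU6-9, a gene of the U6 spliceosomal RNA on chromosome 19, had them in 8981 of 16938 tags at position 893508 (53.0%, interval 52.3 to 53.8%).

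Y RNAs, small cytoplasmic RNAs bound by the Ro protein, followed. RNY1 had deletions in 6956 of 17007 tags at its best site on chromosome 7 (40.9%), RNY3 in 3011 of 5813 (51.8%) and RNY5 in 3287 of 13203 (24.9%). RN7SK, a nuclear RNA that restrains the elongation factor P-TEFb, had them in 3827 of 24357 tags (15.7%), and RNU4-1, a U4 spliceosomal RNA, in 1394 of 3848 (36.2%). S100A6, which encodes a calcium-binding protein, was the only gene among the 10 with the most deletions that is protein-coding and not mitochondrial: at chromosome 1 position 153534610, close to the lower of the gene's listed ends, 1881 of 8631 tags carried the deletion (21.8%, interval 20.9 to 22.7%), and another gene overlaps that position. U6, U4, Y RNA and mitochondrial rRNA sequences have near-identical copies elsewhere in the genome, so the assignment of their tags to 1 copy is uncertain. In all, 298 sites, 185 of them passing, lay on scaffolds without named genes here, 251 of them on KI270733v1.

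Among protein-coding and long noncoding transcripts, the most passing sites were in SMAD3, a transcription factor of the TGF-beta pathway (326 of 472 sites), NEAT1, the RNA scaffold of nuclear paraspeckles (319 of 558), and AKT2, a kinase of the PI3K pathway (299 of 595). TNS3, a focal adhesion protein, had 243 of 393, MACF1, a cytoskeletal linker, 224 of 321, AHNAK 217 of 1472, ACTN4, an actin crosslinker, 208 of 465, and the mitochondrial complex I gene ND5 234 of 1061. Sites in any of these genes need not be in exons. The numbers of passing sites per gene, here and below, were not adjusted for gene length. Strand was not used for naming. In ND5, 173 passing sites lay on the minus strand and 61 on the plus strand. The ND5 site with the most deletions was on the minus strand. Sites on both strands cannot all belong to the ND5 transcript, so its 234 is a count by position. At the site with the most deletions in each of these 8 genes, the share of tags with the deletion ranged from 8.23% in ACTN4 (451 of 5478 tags, interval 7.53 to 8.99%) to 67.4% in NEAT1 (87 of 129 tags, interval 59.0 to 74.9%). RBM42's own gene had 8 passing sites among 20, the best with deletions in 25 of 144 tags on chromosome 19 at position 35633885 (17.4%, interval 12 to 24.4%).

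By class of gene, 86.8% of passing and 80.0% of non-passing sites lay in protein-coding genes. The median coverage was 24 tags in these genes, 265 in small noncoding RNA genes and 1990 on the mitochondrial chromosome, so classes were compared within 6 bins of coverage. The highest bin, 100 or more tags, is open, and coverage can still differ within it. Sites in small noncoding RNA genes passed more often than other sites (odds ratio 1.33, 95% bootstrap interval over genes 1.10 to 1.62, adjusted p = 4.5e-09, Cochran-Mantel-Haenszel test, n = 210997 sites), with 915 passing and 1190 not. This reversed to 0.432 without regard to coverage and to 0.504 with 1 site per gene. Sites in lncRNA genes also passed more often (1.22, interval 1.12 to 1.37, adjusted p = 3.7e-06, n = 210997 sites). Their odds ratio was 0.921 once sites with m/k of 0.5 or more were left out and 0.817 with 1 site per gene, neither past the threshold.

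Sites in pseudogenes passed less often (odds ratio 0.664, bootstrap interval 0.591 to 0.746), with 1791 passing and 1577 not. The few sites in nuclear-encoded rRNA genes, 11 passing and 51 not, had an odds ratio of 0.302 (interval 0.252 to 0.903). They came from only 3 genes, too few for resampling, so no direction is stated. No genes were named on scaffolds, so any rRNA genes there are missing from this class. Its odds ratio does not stand for all nuclear-encoded rRNA. The 298 sites on scaffolds, 185 of them passing, were counted as outside the listed genes. On the scaffold KI270733v1 152 of 251 sites passed, and whether they lie in rRNA was not examined. Sites outside the listed genes had an odds ratio of 1.19 (interval 1.03 to 1.45), which was 1.01 without sites of m/k 0.5 or more and 0.625 with 1 site per window. For protein-coding genes (0.935, interval 0.832 to 1.04), for positions in several protein-coding genes (0.927, interval 0.862 to 1.0004) and for the mitochondrial chromosome (1.23, interval 0.702 to 1.87) the intervals over genes included 1. In 18 finer bins of coverage, chosen after the data were seen, the odds ratio of the mitochondrial chromosome reversed to 0.737. The small p-values of the test for these classes treat all sites as independent.

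**Figure D2:**
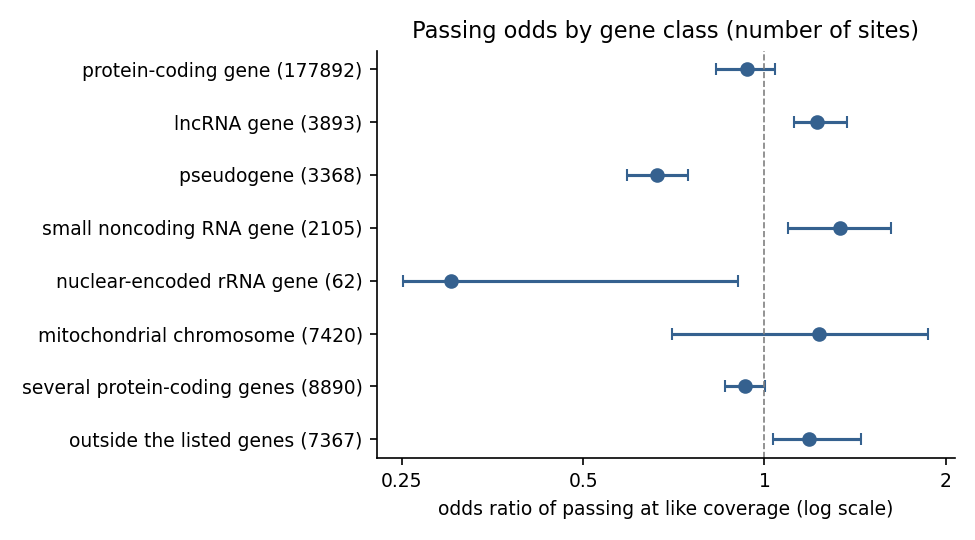
Odds ratio of passing an FDR of 0.05 for sites of each gene class against all other sites, within bins of tag number (log axis), with 95% bootstrap intervals over genes. Numbers in parentheses are sites. Pseudogenes lie below 1 (0.664), and small noncoding RNA (1.33) and lncRNA genes (1.22) above it.

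Passing sites were more numerous at the downstream than at the upstream ends of protein-coding genes, as were listed sites of any kind. The last 200 nt held 6138 passing sites in 2478 genes and the first 200 nt held 1594 in 863 genes, a ratio of 0.260 of first to last (p = 1e-05, permutation test, two-sided, the smallest these resamples can give). More passing sites were at the last end in 2306 genes and at the first end in 596. Coverage differed in the same direction: the median site had 93 tags in the last 200 nt and 26 in the first, and 13727 and 2586 sites of any kind were listed there. Of the listed sites, 61.6% passed in the first 200 nt and 44.7% in the last. Within the same bins of coverage, sites of the first and last 200 nt did not differ detectably in how often they passed (odds ratio 1.05, 95% interval 0.945 to 1.16, p = 0.39, Cochran-Mantel-Haenszel test, n = 2586 and n = 13727 sites). Against other sites, the odds ratio of passing was 0.725 (interval 0.662 to 0.793) for the first 200 nt. It was 0.771 (interval 0.739 to 0.804) for the last 200 nt. These intervals treat sites as independent. A gene's listed ends may not be those of the transcripts that PANC-1 cells make. The RNA was poly(A)-tailed and primed with oligo(dT), and no input library was analysed. The excess at the last end therefore cannot be assigned to binding by RBM42.

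Of the 14 gene lists, 9 had a passing site in every member with any site, and none differed from other genes at like coverage after adjustment by the Cochran-Mantel-Haenszel test (1 had an unadjusted p under 0.05) or by its exact form (also 1). At this threshold 91.1% of all genes with a site had a passing one, which leaves little room for a difference. At the FDR of 0.001, which 73.6% of genes reached, 4 lists differed by the first and 3 by the exact test, whose p is given below for each list. All 33 measured PDAC oncogenes and growth regulators had a passing site, with 299 in AKT2, 119 in the receptor EGFR, 68 in the Hippo pathway coactivator YAP1 and 65 in the cell cycle kinase CDK6. At the stricter FDR 32 of 33 did, against 85.8% at like coverage (exact adjusted p = 0.22).

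All 44 translation factors with a site had a passing one (41 at the stricter FDR, exact adjusted p = 0.26). By number of passing sites within gene bounds, the first 4 were EIF4G3 with 76, EIF4G2 with 62, the helicase DDX3X with 48 and EIF4G1 with 42. EIF4G3 is a long gene (chromosome 1, 20806292 to 21176897), and its number was not adjusted for length. Of 71 ribosomal protein genes, 67 had a passing site and 56 did at the stricter FDR (78.9% against 84.4%, exact adjusted p = 0.30). RPS16 had 80, RPS24 27, RPLP1 18 and RPLP2 16. At RPS16 the best site had deletions in 1011 of 9968 tags (10.1%, interval 9.57 to 10.8%). Compared with genes of like numbers of sites, instead of like highest coverage, ribosomal protein genes with a passing site differed by -4.11 percentage points at FDR 0.05 by a call of the Cochran-Mantel-Haenszel test (adjusted p = 0.019, n = 71 genes) that the exact test did not make (adjusted p = 0.15), and by -13.3 points at 0.001 (exact adjusted p = 0.00027). In 20 strata of highest coverage, chosen after the data were seen, the difference at 0.001 was -9.65 points, past the threshold by the first test (adjusted p = 0.025) and not by the exact test (0.056).

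Splicing proteins had a passing site in 33 of 33 genes, led by SRSF1 with 57, HNRNPA2B1 with 47, HNRNPF with 45 and HNRNPU with 43. Among ribosome biogenesis factors 28 of 29 had one, with 63 in the helicase DDX21, 60 in the methyltransferase FBL, 40 in POLR1A and 39 in NOLC1. For chaperones the number was 32 of 32, with 49 in HSP90AB1, 47 in CANX, 41 in HSP90AA1 and 38 in HSPD1. For glycolytic genes it was 18 of 18, with 51 in GPI, 39 in PFKP, 34 in PKM and 30 in LDHA. For the proteasome it was 30 of 30, with 37 in PSMD11, 36 in PSMC4, 25 in PSMD2 and 24 in PSMA1. At the stricter FDR none of these 5 lists differed, with exact adjusted p-values of 0.36 for splicing proteins, 0.31 for ribosome biogenesis, 0.26 for chaperones, 1.0 for glycolysis and 0.36 for the proteasome.

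Genes of the cytoskeleton and of adhesion had a passing site in 47 of 47 cases, with 208 in ACTN4, 175 in PLEC, 140 in the hyaluronan receptor CD44 and 130 in VCL. At the stricter FDR 45 of 47 (95.7%, Wilson interval 85.8 to 98.8%) had one, against 82.4% of genes at like coverage (exact adjusted p = 0.029). With coverage in 20 strata instead of quintiles, a choice made after the data were seen, the difference was 8.40 points and not past the threshold (exact adjusted p = 0.22). Among genes with like numbers of sites the difference was 1.53 points (exact adjusted p = 0.99).

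Nuclear-encoded genes of oxidative phosphorylation and histone genes had a passing site less often than genes of like coverage at the stricter FDR. For oxidative phosphorylation 28 of 46 genes (60.9%, interval 46.5 to 73.6%) had one, against 86.1% (exact adjusted p = 0.00013), and for histones 22 of 41 (53.7%, interval 38.7 to 67.9%), against 84.1% (exact adjusted p = 3.5e-05). Both differences held among genes with like numbers of sites, at -26.1 points (exact adjusted p = 1.6e-05) and -23.3 points (exact adjusted p = 0.0013), and in 20 strata of highest coverage (exact adjusted p = 5.5e-05 for each). At FDR 0.05 neither differed, with 44 of 46 and 39 of 41 genes (exact adjusted p = 0.89 for each). Members with many passing sites were CYCS, which encodes cytochrome c, with 21, NDUFA10 with 19, ATP5F1B with 14 and NDUFS5 with 13, and, among the histones named here, H1-2 with 14, H1-3 with 10 and H2BC12 with 9.

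RNAs that reside mainly in the nucleus were present in this cytoplasmic precipitate. Of 20 with a site, 17 had a passing one (85%, interval 64.0 to 94.8%) against 96.4% of genes at like coverage, a difference that missed the threshold (adjusted p = 0.081, Cochran-Mantel-Haenszel test, and 0.46, exact test). Without positions in several genes it was -17.1 points, a call of the first test (adjusted p = 0.0013) and not of the exact test (0.12), and at an FDR of 0.01 it was -20.5 points, a call of both (adjusted p = 0.0083 and, exact, 0.041). At the stricter FDR 13 of 20 did, against 85.9%, which passed the threshold by the first test (adjusted p = 0.032) and not by the exact test (0.056), while in 20 strata of coverage both called it (adjusted p = 0.0074 and, exact, 0.031). NEAT1 had 319 passing sites, RN7SK 71, MEG3 52 and RMRP 36. Of the listed Y, vault and 7SL RNAs, a list without tRNAs, all 9 with a site had a passing one (exact adjusted p = 1.0), led by RNY1 with 20, the vault RNAs VTRNA1-2 with 15 and VTRNA1-1 with 14, and RNY5 with 13. The 15 mitochondrial rRNA and protein-coding genes, a list that also lacks tRNAs, did as well (exact adjusted p = 1.0), with 545 in RNR2, 412 in RNR1, 234 in ND5 and 204 in ND4. At the stricter FDR all genes of these lists again had one, with exact adjusted p-values of 0.67 for the small RNAs and 0.35 for the mitochondrial genes.

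**Figure D3:**
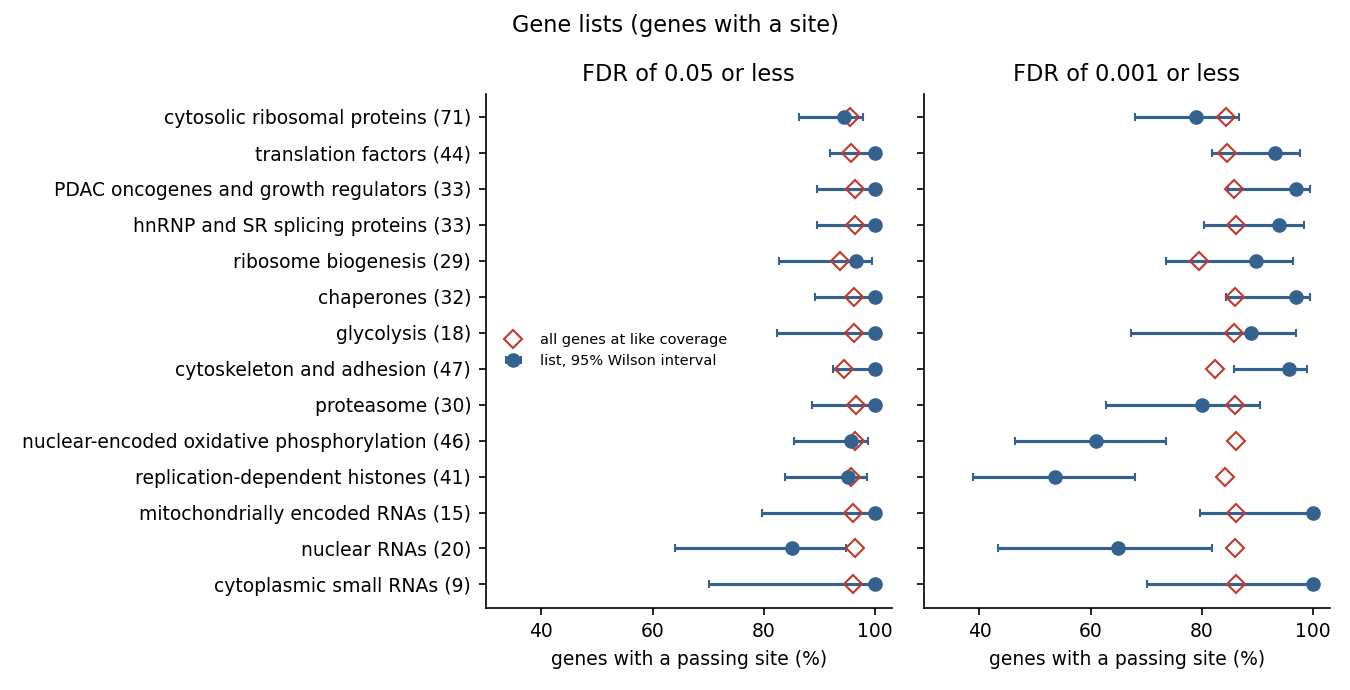
Share of each list's genes with at least 1 passing site (%, points with 95% Wilson intervals) and the share of all genes at like coverage (open diamonds), at FDR 0.05 (left) and 0.001 (right), with the number of genes with a site in parentheses. At 0.001 oxidative phosphorylation (60.9%) and histone genes (53.7%) lie below their diamonds.

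MYC, the transcription factor whose gene lies on chromosome 8 from 127735434 to 127742951, was described after its values were seen. Within its bounds lay 45 sites on the plus strand, of which 14 passed, and 22 on the minus strand, of which none passed. All 22 minus-strand sites lay in the first 1200 nt, with 70 to 214 tags, and 18 of them had 1 deletion each, so this part gave tags of both strands. On the plus strand the first 1200 nt held 23 sites with 83 to 267 tags, of which 17 had 1 deletion each and 1 passed, at position 127736599 with deletions in 21 of 83 tags (25.3%). Downstream of these 1200 nt, all 22 sites were on the plus strand, and 13 passed, at 11 to 89 tags per site. The most deletions were at position 127741370, with 36 of 84 tags (42.9%, interval 32.8 to 53.5%).

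**Figure D4:**
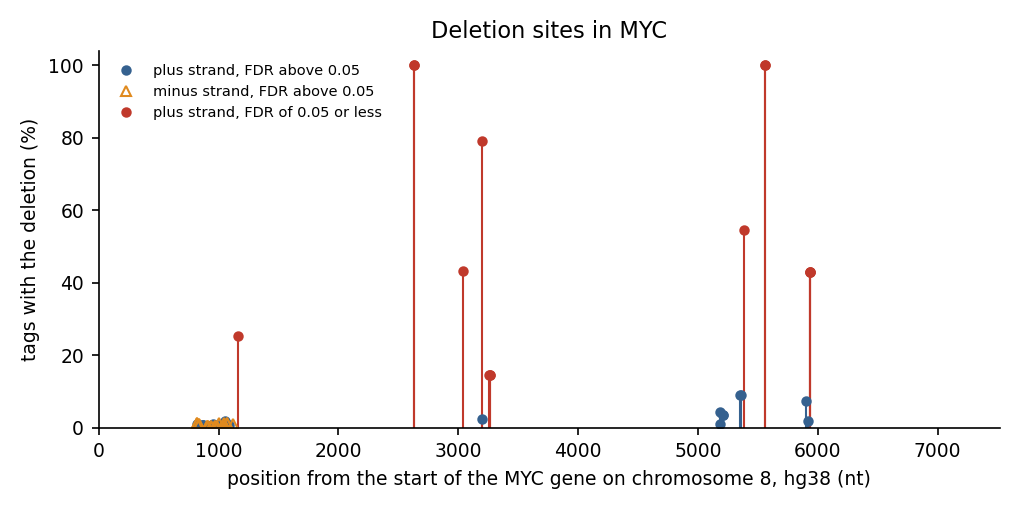
Share of tags with the deletion (%) at each deletion site within MYC, by distance from the start of the gene (nt, hg38), with circles for the 45 plus-strand sites, red for the 14 of them that passed an FDR of 0.05, and open triangles for the 22 minus-strand sites. In the first 1200 nt 1 of 23 plus-strand sites passed, at 83 to 267 tags, and downstream of them 13 of 22, at 11 to 89 tags. Several of the 13 are adjacent positions with the same counts.

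Coverage was concentrated in 1 part of chromosome 19. Over 25 neighbouring protein-coding genes from 38433691 to 39508469, the median of each gene's highest tag number was 335, against 39 over all 10910 protein-coding genes with a site, 8.59 times as high. It was the highest of 10356 such windows, and the highest window that did not overlap it, on chromosome X, had 172. These 25 genes held 1032 passing sites, a median of 21 per gene against 6 over all protein-coding genes with a site. They came from 2514 sites, so a smaller share passed (41.1%) than of all sites (63.8%). ACTN4 and RPS16 lie in the window, and FBL, PSMC4 and AKT2 lie just beyond it. Each of these genes was named above among the members of its list with the most passing sites. Those numbers therefore come from in or next to a region of high coverage.

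**Figure D5:**
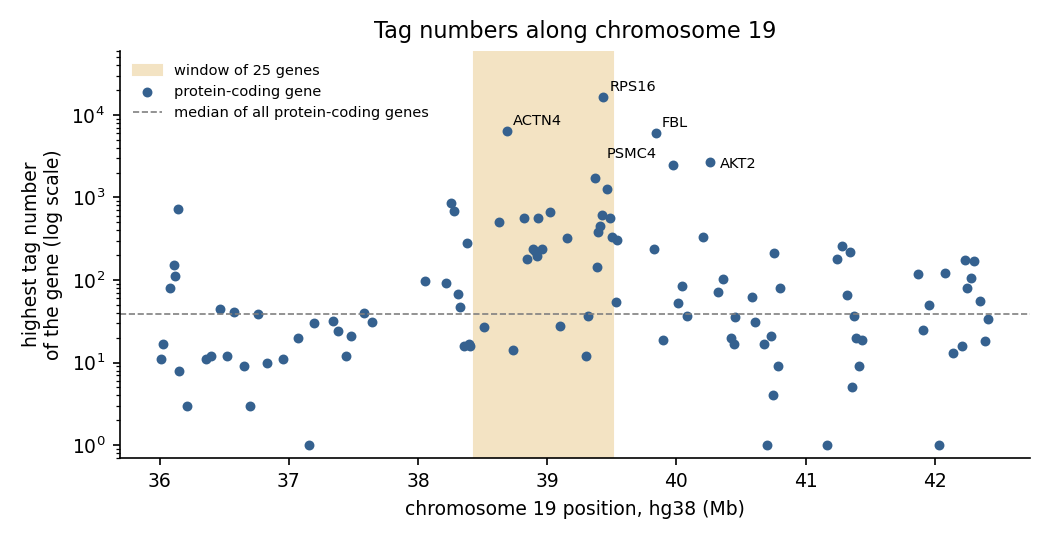
Highest tag number (log axis) of each protein-coding gene with a site along part of chromosome 19 (hg38, Mb), with the window of 25 genes shaded and the median of all protein-coding genes, 39, dashed. The shaded window has a median of 335.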

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

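The alternatives of 1 position per run of adjacent sites, positions in several genes left out, at least 3 tags, finer bins, 20 strata of highest coverage, other end windows, the exact test and those that join FDR 0.001 to another choice were chosen after the data were seen. No paired analysis was possible because the authors pooled the replicates, and no replicate could be left out for the same reason. Leaving out deleted bases in runs of the same base and all those of the 4 results not run (among them 5' UTR precedence over all transcripts) could not be made without a genome sequence and exons. The number of passing sites was 65041 at FDR 0.001, 41413 without sites of m/k 0.5 or more and 85545 with 1 position per run of adjacent sites, and stayed within 1.5 times under the other alternatives. For classes, 72 values kept their direction and side of the threshold, 8 kept only their direction and 12 reversed. At FDR 0.1 the odds ratio of protein-coding genes was 1.03 and that of the mitochondrial chromosome 0.875. Without sites of m/k 0.5 or more, it was 0.921 for lncRNA genes, 1.03 for positions in several protein-coding genes and 1.01 outside genes. Protein-coding genes had 0.973 without the mitochondrial chromosome, 0.976 with 1 position per run and 0.993 in finer bins of k, and positions in several protein-coding genes had 0.966 with 1 position per run. In finer bins the mitochondrial chromosome had 0.737. Without stratification the odds ratios were 1.65 for protein-coding genes, 0.432 for small noncoding RNA genes, 0.20 for the mitochondrial chromosome, 0.967 for several protein-coding genes and 1.002 outside genes. With 1 site per gene, the one with the most deletions, they were 2.07 for protein-coding genes, 0.817 for lncRNA genes, 0.504 for small noncoding RNA genes, 1.60 for the mitochondrial chromosome and 0.625 outside genes. The cause was not tested. Pseudogenes stayed below 1 and past the threshold in every alternative. Nuclear-encoded rRNA genes did so where they had a value, which they lacked with 1 site per gene and without positions in several genes. Apart from 1 site per gene, the p-values behind this threshold treat sites as independent, and no bootstrap over genes was made for the alternatives. The ratio of passing sites in the first to the last 200 nt stayed between 0.159 and 0.320 under all 12 alternatives. Of 14 lists, 4 were called at FDR 0.001, 3 at 0.01, 1 without positions in several genes, 1 with coverage taken as the number of sites, and 3 with both that and FDR 0.001. The exact test called 0, also without positions in several genes or with coverage as the number of sites, the same 3 at FDR 0.01, and 3 at FDR 0.001 with either measure of coverage, which leaves out nuclear RNAs by highest coverage. In 20 strata it called 0, and 3 at FDR 0.001, with differences of -26.0 points for oxidative phosphorylation, -29.5 for histones and -22.9 for nuclear RNAs. Relative to genes of like coverage, the differences in percentage points were 13.4 for the cytoskeleton, -25.2 for oxidative phosphorylation, -30.5 for histones and -20.9 for nuclear RNAs at FDR 0.001. They were -16.4 for oxidative phosphorylation, -19.2 for histones and -20.5 for nuclear RNAs at FDR 0.01, and -17.1 for nuclear RNAs without positions in several genes. With coverage by number of sites they were -4.11 for ribosomal proteins, and with FDR 0.001 as well -13.3 for ribosomal proteins, -26.1 for oxidative phosphorylation and -23.3 for histones. The exact test in quintiles at FDR 0.001 and 0.01 has these same differences. The other 255 list values kept their side of the threshold. Among named genes, 196 numbers of passing sites moved by over 1.5 times and 443 did not. Sites with 1 or 2 tags cannot pass, and the depth per replicate is unknown.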

Other observations

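All tests in this part were chosen after the result was seen, except the one on the 25 genes around AKT2.

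Mitochondrial transcripts gave deletion sites on both strands. The plus strand had 4735 sites with 1486 passing (31.4%) and the minus strand 2685 with 537 passing (20.0%), at median coverages of 2558 and 1426 tags. The rRNA genes were almost wholly on the plus strand, with 412 passing sites in RNR1 there against 0 of 2 sites on the minus strand, and 544 in RNR2 against 1 of 8. Among the protein-coding genes, passing sites on the minus strand outnumbered those on the plus strand in ND5 (173 against 61), in ND6, which the minus strand encodes (47 against 13), and in ND3 (17 against 7). They did so by little in ND4 (105 against 99) and CYTB (30 against 28). No test was made of these numbers.

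Other small RNAs also held passing sites. They were found in 179 of 232 tRNA genes with any site, 102 of 135 snoRNA genes, 18 of 22 snRNA genes, 3 of 3 vault RNA genes and 4 of 4 Y RNA genes. Of all genes with a site, 91.1% had a passing one, and no test against that share was made here. Since small genes took precedence and strand was not used, some of these sites may belong to overlapping genes. The most tags with a deletion at 1 position were 795 in tRNA genes and 147 in snoRNA genes, far below the 22108 of RMRP. Many tRNA genes have near-identical copies, so the assignment of tags to 1 of them is uncertain.

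The number of deletions at a site followed its coverage only weakly. Over all listed sites, the median m was 10 (quartiles 3 and 21) at 100 to under 200 tags and 13 (quartiles 5 and 28) at 500 to under 2000 tags, a 1.30-fold rise (95% bootstrap interval over genes 1.18 to 1.40), while the median k rose 6.45-fold, which argues against 1 deletion rate shared by all sites and independent tags. Among sites with at least 5 deletions and 100 tags, 89.1% (Wilson interval 88.8 to 89.5%) had m/k under 0.2, which argues against deletions carried by the cell line, near allele fractions, at sites with 100 or more tags. The share was 6.22% at 20 to under 50 tags and 38.5% at 50 to under 100 tags, where the minimum of 5 deletions keeps it low, so carried deletions stay open below 100 tags. Copies of single molecules counted as separate tags could give such values and would make the FDR too small, but the 1.30-fold rise is the pattern itself and no evidence for them.

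A position within RNR2, at which the human mitochondrial reference is known to hold a placeholder for a missing base, had deletions in 52808 of 64954 tags (81.3%, Wilson interval 81.0 to 81.6%). It ranked 1 by m/k among the 5579 mitochondrial sites with at least 1000 tags. Reads that lack the placeholder could be aligned with a gap there, but the remaining tags had no deletion at the position, and the sequence of the build was not used here, so this stays open. Positions 3180 and 3181 came next, at 76.5% and 76.4%, and position 11365 in ND4 followed at 37.1%, with no explanation tested.

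The high coverage on chromosome 19 next to AKT2 invites a comparison with the known gain of the AKT2 region in PANC-1 cells, which could raise the RNA of neighbouring genes together. Over the 25 genes centred on AKT2, the median highest tag number was 1.59 times that of all protein-coding genes (95% bootstrap interval 0.923 to 6.13), and this window ranked 976 of 10356 (percentile 90.3). A gain was set beforehand to need over 2 times and the top 1 percent of windows, which was not met, while the interval does not exclude a gain either. The window was uneven. Upstream of AKT2, FBL had 5982 tags, PSMC4 2502 and MAP3K10 328, but ZNF780A had 37 and FCGBP 19. Downstream of AKT2 the highest was 210 in SNRPA, and the next gene, C19orf47, had 71. A window centred on AKT2 could miss a gain that ends near it, so this test cannot decide. In the window with the highest median, 335, which begins upstream, no random order of the genes in 1000 draws gave a window above 164, which argues against chance order. Without DNA copy number or an input library, a gain, high transcription of adjacent genes and binding by RBM42 cannot be told apart.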
